A study of Mus musculus with 8 samples.

How the data were processed

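Gene expression was measured in mPAC cells, a mouse pancreatic ductal cell line, infected with an adenovirus that carried human neurogenin3, mouse NeuroD1 or, as the control, beta-galactosidase. Per the labels' protocols, wells of 500000 cells received virus at a multiplicity of infection of 50 for 2 h and were cultured for a further 46 h, and 3 wells were pooled into each RNA sample. Each of 8 cDNA arrays set 1 factor RNA, labelled with Cy5, against 1 beta-galactosidase RNA, labelled with Cy3. Every array had this dye orientation. A dye effect of a single gene therefore stays in a ratio tested against 0, and it cancels in the difference of the factors.

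Groups were taken from the array titles, which named neurogenin3 on 5 arrays and neuroD1 on 3. For array 1a of the neurogenin3 group the title and the treatment protocol named neurogenin3, whereas the source name of its Cy5 channel named neuroD1. The title was followed, and the array was checked against the values below. Arrays 1a and 1b carried 1 experiment number and were averaged, which left 4 neurogenin3 and 3 neuroD1 experiments. The labels do not say whether experiments were separate cultures, so the p-values measure only the spread between these experiments, which may be technical.

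The authors deposited a table for each factor with the log2 ratio of Cy5 over Cy3 and the mean log2 signal of every spot. Its log2 ratios had medians of -0.10 to 0.19 in bands of signal, without the trend of the series table below, and were read as normalized within each array. The method is not given in the sources used here. The spread of the ratios differed between arrays, with no sign of a scaling to 1 spread. A table of the whole series, also deposited, held log2 ratios with no such normalization, with array medians from -0.45 to -0.10 and a trend with signal, in which ratios with no finite value stood at 1 fixed high number that was read as missing. The authors also deposited a combined table with a mean log2 ratio, a p-value, an adjusted p-value and test scores per spot. Its means equalled the mean over all 5 or all 3 arrays of the normalized ratios. The tool behind these p-values and scores is not given in the sources used here. The normalized log2 ratios of the factor tables are the values used throughout. The plan written before the data were examined had named the series table first and the factor tables as its alternative. The order was turned round once the series table proved not to be normalized, and the results from the series table are given as an alternative chosen after seeing the data.

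Each array held 22272 cDNA probes and 960 spots marked empty. The platform annotation gave 18738 probes 1 gene symbol, 67 several and 3467 none. Symbols were updated through the gene identifier with a mouse gene table, which did not hold the identifier of 612 of the probes, and those kept their older symbol. Probes with several symbols were left unnamed. Probes of a gene were averaged, which mattered for 4233 of the tested genes, and where the probes of a named gene differed by over 0.5 in log2 ratio or in sign, their values are given beside its own. The averaging was within each experiment over the probes with a value there. The value of a gene can therefore differ from the mean of its probe values. Genes with a value in at least 2 experiments of each factor were kept, 10955 of 11015 with a symbol.

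Ratios were tested with limma 3.58.1 in R 4.3.3. All 7 experiments were fitted together with a mean for each factor (lmFit and eBayes, 2.83 prior degrees of freedom), and each mean was tested against 0 and against the other. The beta-galactosidase RNA of an array is its own control, and its culture-to-culture spread enters only through the ratios. P-values were adjusted by the Benjamini-Hochberg method, and every adjusted p below for a gene is limma's, with a call at adjusted p under 0.05. In all, 15 lists of genes (islet transcription factors, islet hormones and granule proteins, exocytosis, neuronal cytoskeleton, glucose sensing and ion channels, Notch pathway, E proteins and Id factors, cell cycle, cell cycle inhibitors, duct and epithelial genes, acinar and mesenchymal markers as other cell types, interferon response, stress response and housekeeping genes) were fixed before the data were examined. They were tested with limma's camera at an inter-gene correlation of 0.01 and adjusted over the lists, and again with an estimated correlation and with fry. These set tests took only genes with a value in every experiment fitted, 10174 with all 7 experiments. They could therefore hold fewer members than the counts and medians of a list, as for the cell cycle with 38 of 40.

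Genes were named by a rule fixed in the same way. It took the 12 highest and 8 lowest log2 ratios among called genes with the same sign in every experiment of the group, up to 4 called members of each list with the largest ratios (or the 2 with the smallest p where none was called), and Neurog3 and Neurod1. For the difference of the factors, where fewer than 5 genes were called, it took the 10 genes with the smallest p. Not every gene so taken is given below, and those given for a list can leave out larger ratios of either sign. A gene was taken as not above background in a channel when its signal there did not exceed the 95th percentile of the empty spots on any array of the group. Its fold is then given as a bound, the mean of the bright channel over the higher of that percentile and the measured signal. Channel values come from the ratio and the mean signal, and they remain open to dye bias.

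The limma fit was tested on simulated data with the spread of each of the 10955 genes in each group and 50 genes changed by each of 4 known amounts. For neurogenin3 against control it recovered 72.0% of genes changed by a log2 ratio of 1 and 94.0% of those changed by 2. Of its 206 calls, 26.7% were of unchanged genes, the neurogenin3 experiments spreading more widely than the shared estimate. With neurogenin3 fitted alone, 46.0% of the genes changed by 1 and 74.0% of those changed by 2 were recovered, and 7.56% of 119 calls were of unchanged genes. For neuroD1 against control the shared fit recovered 68.0% and 96.0% at these sizes, with 5.30% of 151 calls unchanged. For the difference of the factors it recovered 48.0% and 88.0%, with 5.38% of 130 calls unchanged.

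The alternatives fixed before the data were examined left out array 1a, kept arrays 1a and 1b apart, fitted each group alone, used robust eBayes, centred or scaled the arrays, changed the filter on missing values, left out the dimmest 25% of genes, tested each probe, took the median of probes, added the experiment number as a block, left out each experiment in turn and used the authors' deposited statistics. Array weights, a prior variance with a signal trend, the removal of array 1a together with neurogenin3 experiment 4, the fit of neurogenin3 alone without experiment 4, and the set tests without the genes that the virus delivered were added after seeing the data. The number of arrays limits the precision of every value.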

Results

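Transcript levels in mPAC cells, a mouse pancreatic ductal cell line, were compared 48 h after infection with adenovirus for neurogenin3 or NeuroD1, 2 basic helix-loop-helix transcription factors of the islet lineage, with those in cells that received a beta-galactosidase virus. The stated purpose of the design was to compare the fold changes produced by the 2 factors. Neurogenin3 was measured in 4 experiments on 5 arrays and neuroD1 in 3 experiments on 3 arrays. Neurogenin3 array 4 stood apart. It had no ratio for 11.0% of the cDNA probes against 1.29% to 5.16% on the other arrays, a median log2 signal of 5.48 against 6.53 to 6.80 on the other arrays, and an SD of its log2 ratios of 0.95 against 0.43 to 0.82. The median gene had an SD of 0.31 between the neurogenin3 experiments, 0.19 without experiment 4, and 0.13 between the neuroD1 experiments.

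The introduced factors were read first, as a check of the labels. Neurog3 had a log2 ratio of 4.94 on array 1a, 5.05 on 1b, 4.19 on 2, 4.48 on 3 and 2.74 on 4, and between -0.01 and 0.09 on the neuroD1 arrays. Neurod1 had a log2 ratio of 5.11, 3.85 and 4.23 on neuroD1 arrays 3, 4 and 5. The 3.85 also averages a dim probe, at -0.25, that had no value on the other neuroD1 arrays. The brighter probes read higher than 3.85 there, so this value does not make array 4 the weakest. Array 1a, whose labels name both factors, had a Neurod1 log2 ratio of 0.92 and thus read as a neurogenin3 array. Across genes, which are not independent replicates, array 1a correlated with 1b at r = 0.575, with the other neurogenin3 arrays at 0.467 to 0.554 and with the neuroD1 arrays at 0.504 to 0.559, so that the genome-wide profile did not separate the factors. The probes may read both the viral transcript and the cell's own, since probe sequences were not used here.

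**Figure D1:**
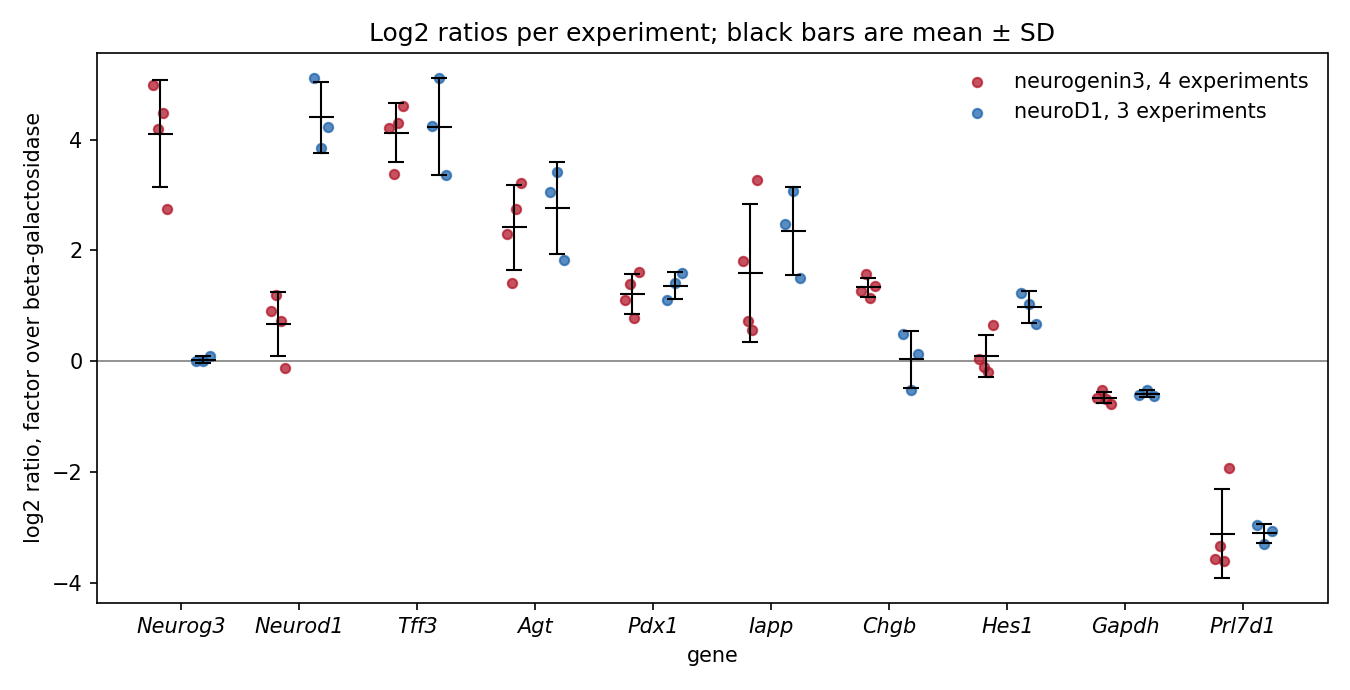
Log2 ratio of factor over beta-galactosidase (y axis) for 10 genes (x axis), with 1 point per experiment (red, 4 neurogenin3 experiments; blue, 3 neuroD1 experiments) and black bars for mean ± SD. Neurog3 and Neurod1 separate the groups, whereas Tff3, Agt, Pdx1, Gapdh and Prl7d1 lie at like ratios with both factors.

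Neurogenin3 raised and lowered genes of several kinds relative to beta-galactosidase. Tff3, a secreted trefoil peptide of mucosal epithelia, had a log2 ratio of 4.12 ± 0.53 (SD, n = 4), 17.4-fold, and lay beside Neurog3 itself at 4.10 ± 0.96 (SD, n = 4). Agt, which encodes angiotensinogen, rose to 2.42 ± 0.77 (SD, n = 4), Alb, which encodes albumin, to 1.92 ± 0.73 (SD, n = 4), and Sprr2a1, a cornified envelope gene, to 1.88 ± 0.43 (SD, n = 4). Hmgn5, a nucleosome-binding protein gene, reached 2.44 ± 1.39, Fcmr 1.76 ± 0.70 and Atoh8, another basic helix-loop-helix factor, 1.76 ± 0.60 (SD, n = 4 for each). Among the lowest were Tex24 at -3.36 ± 1.88, Prl7d1, of the prolactin family, at -3.11 ± 0.80, Paf1 at -2.69 ± 1.53, Slurp1 at -2.57 ± 0.54 and 2310061N02Rik at -2.14 ± 0.94 (SD, n = 4 for each). The 5 probes of Prl7d1 lay between -3.23 and -2.97, the probes of Agt at 1.96 and 2.87, and those of Neurog3 at 3.75 and 5.03. All genes in this paragraph so far also passed with neurogenin3 fitted alone. Etv1 at 1.66 ± 1.22 (SD, n = 4), Smim13 at 1.69 ± 1.29 (SD, n = 3), Klk12 at -2.20 ± 1.33 (SD, n = 4) and Krt32 at -2.85 ± 2.12 (SD, n = 4) passed only with the spread shared between groups. Etv1 stood at 1.07 without experiment 4 and Smim13 at 1.01 without experiment 2, both still past the threshold. Ebf3, measured in 2 experiments, also passed, with a control channel not above the empty spots and therefore no fold, and Unc5c was at least 2.07-fold lower, with its factor channel not above them and a measured log2 ratio of -2.39, or -1.47 without experiment 3. The factor channels of Slurp1, Tex24, Klk12, 2310061N02Rik, Paf1 and Krt32 averaged log2 signals of 2.74 to 3.64. On the neurogenin3 arrays the 95th percentile of the mean log2 signal of empty spots was 2.23 to 5.59, so the size of these falls is uncertain.

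Some genes of the islet programme were among those that rose with neurogenin3. Over all genes 1550 of 10955 rose and 2033 fell in the same fit, and the counts of each list are to be read against these. Of 23 measured islet transcription factors 5 rose and none fell, the same counts as adjusted over the list alone, and 1 of the 5 was Neurog3, which the virus delivered. Pdx1, which is required for pancreas and beta cell development, rose to 1.22 ± 0.36 (SD, n = 4, adjusted p = 0.00406), and its 3 probes gave 0.69 to 1.57. Isl1 stood at 1.21 ± 0.38 (SD, n = 2, adjusted p = 0.0133), in 2 of 2 experiments. With values missing, it was not in the set test, which held 21 of the 23 members. The list's shift missed the threshold (camera adjusted p = 0.0574, and adjusted p = 0.463 with an estimated correlation), while fry, which does not compare a list with other genes, called it (adjusted p = 0.0293). It passed without experiment 1 (adjusted p = 0.0350) or experiment 3 (adjusted p = 0.0303), but not there with an estimated correlation (adjusted p = 0.439 and 0.525). Without Neurog3, a test chosen after seeing the data, the list had a mean of 0.27 in place of 0.44 (camera adjusted p = 0.132). Neurod1, a known downstream factor, stood at 0.67 ± 0.57 (SD, n = 4, adjusted p = 0.0717), higher in 3 of 4 experiments. It passed at 0.94 without experiment 4 (adjusted p = 0.0278). Its probes disagreed, with means of 2.08, 0.31 and 0.29, and the last of these, with a log2 signal of 2.09, read -0.25 with neuroD1. Of 21 islet hormone and granule genes 3 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.911). The median of this list was -0.03 and its mean 0.09, with a test direction of down. Chgb, which encodes chromogranin B of secretory granules, rose to 1.33 ± 0.18 (SD, n = 4), and Iapp, which encodes islet amyloid polypeptide, to 1.59 ± 1.25 (SD, n = 4), a call lost without neurogenin3 experiment 1 or 4 or neuroD1 experiment 3, with a value of 1.03 without neurogenin3 experiment 4. Gip, at -0.70 ± 0.24, and Tac1, at -0.97 ± 0.50 (SD, n = 4 for each), fell. Probes disagreed in size for Chgb (0.92 and 1.74), Gip (-0.24 and -1.16) and Tac1 (-0.51 and -1.43). Slc2a2, which encodes the glucose transporter of beta cells, rose to 0.69 ± 0.31 (SD, n = 4), while 3 of the 10 genes of glucose sensing and ion channels fell, among them Pck2 at -0.36 ± 0.22 (SD, n = 4), with the same counts adjusted over the list alone (camera adjusted p = 0.450). Of 15 exocytosis genes 4 rose and 3 fell, 6 and 4 adjusted over the list alone (camera adjusted p = 0.596). Rph3al, at 1.31 ± 0.57, rose and Rims1, at -1.21 ± 0.38 (SD, n = 4 for each), fell. None of 18 neuronal cytoskeleton and adhesion genes rose and 5 fell, also adjusted over the list alone, with Gdap1 at -1.06 ± 0.66, on probes at -0.47 and -1.64, and Nrcam, a cell adhesion molecule, at -0.76 ± 0.22 (SD, n = 4 for each). The shift of this list missed the threshold (camera adjusted p = 0.107; fry adjusted p = 0.0211) and passed without experiment 1 (adjusted p = 0.0411), where it was lost with an estimated correlation (adjusted p = 0.418). With neurogenin3 fitted alone the calls of Isl1, Iapp, Tac1, Slc2a2, Pck2 and Gdap1 were lost.

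At camera's preset correlation 4 lists were shifted upwards with neurogenin3, each at camera adjusted p = 0.0129. With an estimated correlation none of the 4 held (adjusted p = 0.437 for each), whereas fry called each (adjusted p = 0.00188 to 0.0211). A higher correlation was not the whole reason for the loss. For the E proteins and Id factors it was estimated at -0.0247, below the preset 0.01, yet the camera p rose from 0.00344 to 0.0307. In the cell cycle list 14 of 40 genes rose and 2 fell, with 14 and 3 adjusted over the list alone. Pcna, the replication clamp, rose to 0.80 ± 0.31 and the clamp loader gene Rfc5 to 0.92 ± 0.68, with probes at 0.54 and 1.10 and a value of 0.59 without experiment 4, while the mitotic genes Plk1, at -0.77 ± 0.48, and Hmmr, at -0.82 ± 0.60 (SD, n = 4 for each), fell. In the interferon list 9 of 21 rose and 2 fell, with 10 and 2 adjusted over the list alone, and Ifi27 stood at 0.83 ± 0.52, Ly6e at 0.82 ± 0.49 and Isg20 at -0.67 ± 0.28 (SD, n = 4 for each). The brighter probe of Ly6e read 1.15 and the other 0.15, and the 5 probes of Isg20 lay between -1.05 and -0.39. In the stress list 7 of 18 rose and 1 fell, also adjusted over the list alone. Calr, the endoplasmic reticulum chaperone calreticulin, rose to 1.21 ± 0.19, and Hspa5, which encodes the chaperone BiP, to 0.65 ± 0.47 (SD, n = 4 for each). Among E proteins and Id factors 3 of 5 rose, also adjusted over the list alone, and Id3, an inhibitor of basic helix-loop-helix factors, stood at 0.94 ± 0.21 (SD, n = 4). Without experiment 4 the stress list missed the threshold (adjusted p = 0.0741). With neurogenin3 fitted alone Pcna, Calr and Id3 kept their calls and the other genes named here lost theirs. The control cells also carried an adenovirus.

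The remaining lists moved both ways with neurogenin3. In the Notch list 3 of 19 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.450), with Numb, a Notch antagonist, at 1.49 ± 0.67, on probes at 1.65 and 1.00, and Rbpj, the DNA-binding partner of Notch, at -0.56 ± 0.18 (SD, n = 4 for each). Of 18 duct and epithelial genes 6 rose and 4 fell, 7 and 4 adjusted over the list alone (camera adjusted p = 0.517), with Cd24a at 0.84 ± 0.48, Lamb3 at -0.89 ± 0.24 and Anxa3 at -0.77 ± 0.26 (SD, n = 4 for each). For markers of other cell types, 2 of 25 acinar genes rose and 6 fell (camera adjusted p = 0.450), and 3 of 16 mesenchymal genes rose and 2 fell (camera adjusted p = 0.911), with the same counts adjusted over each list alone. Vim, the intermediate filament of mesenchymal and cultured cells, fell to -0.79 ± 0.19 (SD, n = 4). Clps, an acinar gene, was called higher at 0.52 ± 0.33 (SD, n = 4) although its brightest probe read -0.54 and the others 0.10 to 1.21. One cell cycle inhibitor of 11 rose, Gadd45g at 0.68 ± 0.12 (SD, n = 4), and 1 fell, and adjusted over the list alone 1 rose and 0 fell (camera adjusted p = 0.678). Of 13 housekeeping genes 2 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.582), and Gapdh, the glycolytic enzyme, was at -0.66 ± 0.10 (SD, n = 4). With neurogenin3 fitted alone the calls of Rbpj, Cd24a and Clps were lost.

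The genes changed by neurogenin3 numbered 3583 of 10955 tested, 1550 higher and 2033 lower, and 119 and 315 of these by at least 2-fold. The count rests on the spread shared with the neuroD1 arrays. Neurogenin3 fitted alone gave 625 genes, 153 higher and 472 lower, of which 624 were among the 3583. Without experiment 1 the count was 1958 and without experiment 2 it was 2370, and with neurogenin3 fitted alone without experiment 4, chosen after seeing the data, it was 4 (Neurog3, Alb, Prl7d1 and Anxa10, the last named after its value was seen). Of the genes named above, Iapp, Smim13, Clps, Plk1, Pck2, Ly6e, Rbpj and Hspa5 lost their calls without experiment 1, Unc5c, Clps and Rfc5 without experiment 2, Pck2 and Rbpj without experiment 3, and Iapp, Krt32, Clps, Hmmr and Ly6e without experiment 4. Pck2 lost its call without any 1 of the neuroD1 experiments, and Clps without neuroD1 experiment 3 or 4.

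With neuroD1 many of the same genes passed, 284 of its 300 calls being shared with neurogenin3. Tff3 had a log2 ratio of 4.23 ± 0.87 (SD, n = 3), 18.8-fold, next to Neurod1 itself at 4.40 ± 0.65 (SD, n = 3), whose probes read 5.29, 4.87 and, for the dimmest, -0.25. The dimmest had a value in neuroD1 experiment 4 alone, and it lowers the mean of the gene. Agt rose to 2.76 ± 0.84, Sprr2a1 to 2.43 ± 0.28 on probes between 2.03 and 2.60, Alb to 2.36 ± 0.45, Fcmr to 1.70 ± 0.27 and Sting1, an innate immune adaptor gene, to 1.41 ± 0.18 (SD, n = 3 for each). Sh3bgrl3 stood at 1.35 ± 0.43, Cox11 at 1.21 ± 0.23 and Glod5 at 1.19 ± 0.30 (SD, n = 3 for each), and 4932443L11Rik was at least 1.30-fold higher, its control channel not being above the empty spots. Prl7d1 was the lowest at -3.11 ± 0.18 (SD, n = 3). Also among the lowest were Otud3 at -1.96 ± 1.13, Slc6a21 at -1.82 ± 1.14, Nkx2-9 at -1.80 ± 0.62, Lcn5 at -1.75 ± 0.55, Ero1a, an endoplasmic reticulum oxidase gene, at -1.68 ± 0.69 and Lce1e at -1.65 ± 0.59 (SD, n = 3 for each). The factor channel averaged a log2 signal of 1.64 for Otud3 and 2.87 for Nkx2-9. On the neuroD1 arrays the 95th percentile of the mean log2 signal of empty spots was 2.56 to 3.08, so the size of these 2 falls is uncertain. Slurp1 was at -1.90 ± 0.05 (SD, n = 2). Slc6a21 stood at -1.17 without experiment 4, where its call was lost.

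Of the islet transcription factors 2 of 23 rose with neuroD1, namely Neurod1 and Pdx1, also adjusted over the list alone (camera adjusted p = 0.543, direction up, with a median of -0.01 and a mean of 0.21). Without Neurod1, which the virus delivered, a test chosen after seeing the data, the list had a mean of 0.02 (camera adjusted p = 0.737). Pdx1 stood at 1.37 ± 0.25 (SD, n = 3, adjusted p = 0.0198), higher in 3 of 3 experiments, with probes between 0.86 and 1.82. Neurog3 stood at 0.03 ± 0.06 (SD, n = 3, adjusted p = 0.977), on probes at 0.53 and -0.29. None of 21 hormone and granule genes passed over all genes, and 1 rose adjusted over the list alone (camera adjusted p = 0.680, direction down, with a median of -0.09 and a mean of 0.01). Iapp had a log2 ratio of 2.35 ± 0.79 (SD, n = 3, adjusted p = 0.0544), and passed without neurogenin3 experiment 4. Slc2a2 rose to 0.76 ± 0.14 (SD, n = 3), the only call among 10 genes of glucose sensing and ion channels, where adjusted over the list alone 1 rose and 1 fell (camera adjusted p = 0.680). No exocytosis gene of 15 passed, with 2 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.680, direction up, with a median of 0.05 and a mean of -0.02). One of 18 neuronal genes fell, Nrcam at -0.74 ± 0.14 (SD, n = 3), 2 adjusted over the list alone (camera adjusted p = 0.0661, fry adjusted p = 0.0391, and camera adjusted p = 0.0456 without neurogenin3 experiment 2, where it was adjusted p = 0.714 with an estimated correlation). In the Notch list Hes1, a Notch target, rose to 0.98 ± 0.28 and Rbpj fell to -0.90 ± 0.40 (SD, n = 3 for each), 2 higher and 1 lower of 19 adjusted over the list alone (camera adjusted p = 0.269). The Hes1 value joins a probe at 2.13 with one at -0.17, so the gene's direction is not settled.

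The interferon list was shifted upwards with neuroD1 (camera adjusted p = 0.00072), although no member passed over all genes and 6 rose and 1 fell of 21 adjusted over the list alone. With an estimated correlation this call was lost (adjusted p = 0.331), and with fry it passed (adjusted p = 0.0391). Its smallest p-values belonged to Rsad2 at 0.49 ± 0.20 and B2m at 0.51 ± 0.17 (SD, n = 3 for each), and both passed without neurogenin3 experiment 4. Without neurogenin3 experiment 2 the E protein list (adjusted p = 0.0416) and the stress list (adjusted p = 0.0456) passed as well, and the E protein list also without neuroD1 experiment 3 (adjusted p = 0.0362). With an estimated correlation these calls were lost too (adjusted p = 0.714, 0.781 and 0.423 in the same order). In the stress list Calr rose to 0.84 ± 0.14 (SD, n = 3), 1 of 18, with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0626). No cell cycle gene of 40 passed (camera adjusted p = 0.497), with Ccne2 at 0.41 ± 0.15 and Bub1 at -0.42 ± 0.15 (SD, n = 3 for each) and Ccne2, whose brighter probe read 0.04 and the other 0.78, passing without neurogenin3 experiment 4, nor did any of 5 E protein and Id genes (camera adjusted p = 0.0626, fry adjusted p = 0.0391), 11 cell cycle inhibitors (camera adjusted p = 0.680) or 25 acinar genes (camera adjusted p = 0.680), over all genes or adjusted over the list alone. Of the duct and epithelial genes Anxa3, at -0.68 ± 0.14, and Lamb3, at -0.74 ± 0.32 (SD, n = 3 for each), fell, 2 of 18, with 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.692, direction down, with a median of 0.01 and a mean of -0.05). Vim fell to -0.67 ± 0.19 (SD, n = 3) as the single call among 16 mesenchymal genes, also adjusted over the list alone (camera adjusted p = 0.994, direction up, with a median of 0.05 and a mean of -0.03), and Gapdh to -0.59 ± 0.06 (SD, n = 3) among 13 housekeeping genes, with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.994, direction up, and fry adjusted p = 0.0391, direction down).

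The genes changed by neuroD1 numbered 63 higher and 237 lower, 20 and 70 of them by at least 2-fold. Fitted alone, which takes the smaller spread of these 3 experiments, it had 1026 higher and 1694 lower, including each of the 300, and these 2720 exceeded the 625 of neurogenin3 fitted alone. Leaving out neuroD1 experiment 3, 4 or 5 left 2, 2 and 5 genes, leaving out neurogenin3 experiment 1 or 2 gave 77 and 199, and leaving out neurogenin3 experiment 4 gave 1785. The 2 genes left without experiment 3 were Neurod1 and Fancd2, those without experiment 4 Neurod1 and Tff3, and the 5 without experiment 5 Neurod1, Tff3, Sprr2a1, Otud3 and 4932443L11Rik, with Fancd2 named after its value was seen. Each call of neuroD1 named above other than that of Neurod1 was thus lost when at least 1 neuroD1 experiment was left out. Of its 29 named calls, 11 were kept without neurogenin3 experiment 1, 20 without experiment 2, 23 without experiment 3 and 29 without experiment 4. In the authors' deposited table, which tests each probe, 917 probes were higher and 1528 lower for neurogenin3 and 1971 higher and 2883 lower for neuroD1.

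**Figure D2:**
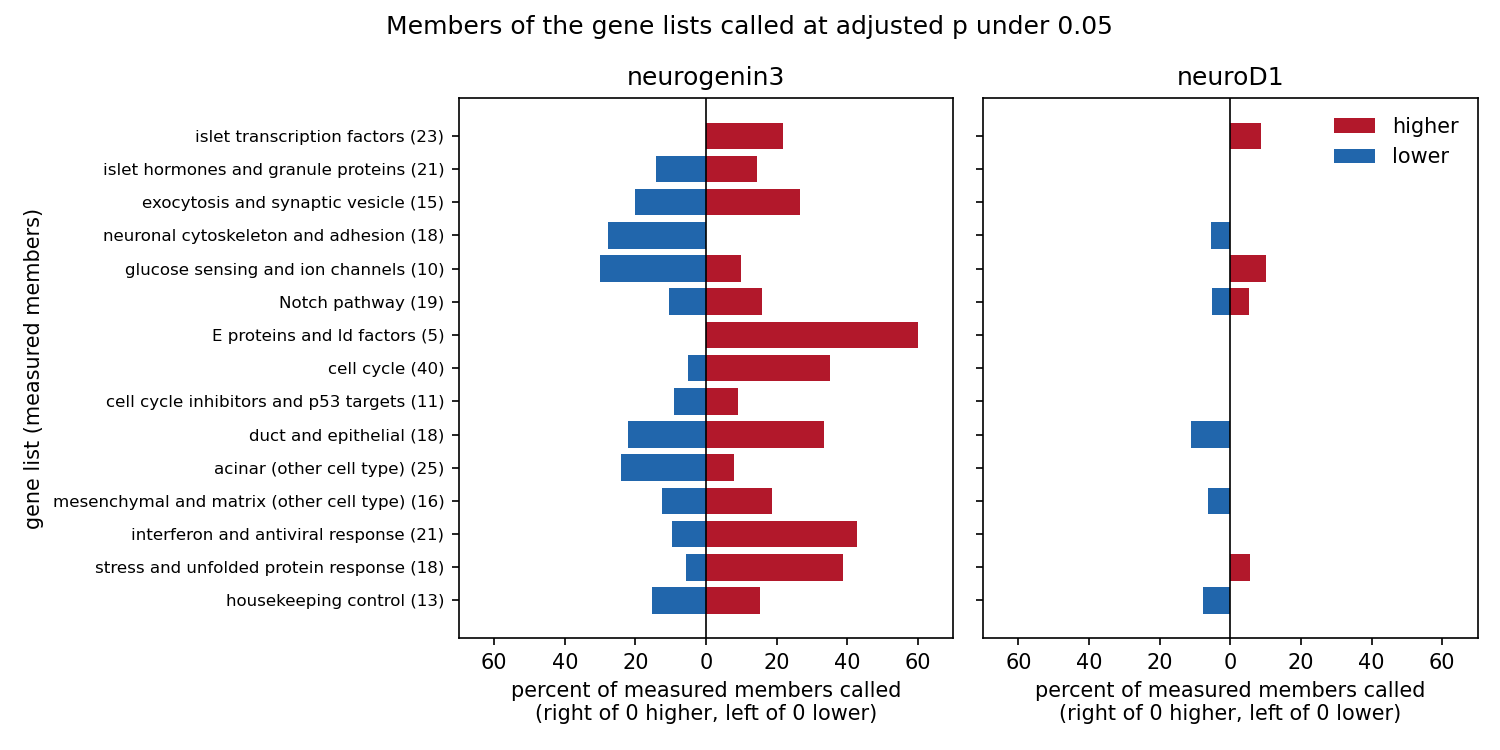
Percent of the measured members of each gene list (y axis, with the number measured) called higher (red, right of 0) or lower (blue, left of 0) at adjusted p under 0.05, for neurogenin3 (left) and neuroD1 (right). For neurogenin3, 14 of 40 cell cycle genes and 9 of 21 interferon genes lie on the higher side, and for neuroD1 few members of any list pass. Both panels use the spread shared between the groups, so their heights do not compare the factors. Over all genes the order of the calls was reversed with each group fitted alone (625 for neurogenin3 against 2720 for neuroD1).

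The profiles of the 2 factors were alike. Across 10955 genes the mean log2 ratios correlated at r = 0.779 (Spearman rho = 0.800), and 82.0% of genes had the same sign, against 59.3% in simulated unchanged groups that share control RNA. Of the genes called higher, 52 were shared where independent lists would share 8.91, and of those called lower 232 where they would share 44.0, with 0 called in opposite directions. Both calls of a gene used 1 shared estimate of its spread, so the lists were not independent. The excess over independent lists therefore does not measure the likeness. The shared genes include Tff3, Agt, Alb, Sprr2a1, Fcmr, Pdx1, Slc2a2 and Calr on the higher side and Prl7d1, Slurp1, Rbpj, Nrcam, Vim and Gapdh on the lower. Unchanged groups that share control RNA in the experiments numbered 3 and 4 gave a simulated r of 0.190 and a covariance of 0.0063, against an observed covariance of 0.140. Between experiments that share no number, neurogenin3 1 and 2 and neuroD1 5, r was 0.670 and the covariance 0.134. Means of fewer experiments hold more noise, which lowers r, so the lower r does not measure a part from shared controls. The common dye orientation enters both profiles, and part of the likeness may come from it or from shared controls.

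**Figure D3:**
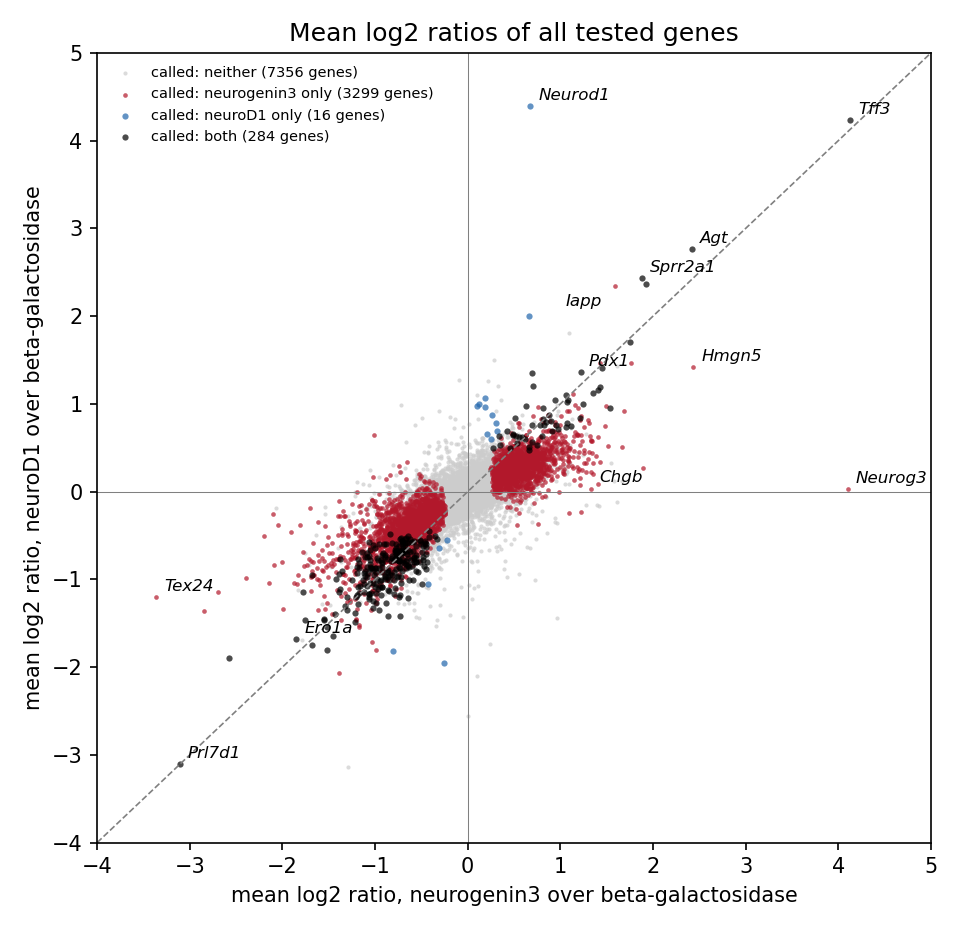
Mean log2 ratio with neuroD1 (y axis) against that with neurogenin3 (x axis) for 10955 genes, coloured by the calls at adjusted p under 0.05, with the line of equal ratios dashed. Over all genes r was 0.779, and Neurog3 and Neurod1 lie far from the line.

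Setting the factors directly against each other, limma called 0 genes, with 380 at an unadjusted p under 0.05 where 548 would be by chance. Without neurogenin3 experiment 4 it called 1, Neurog3 at 4.53 (adjusted p = 0.00286). Neurod1 was called with the median of the probes of a gene (-4.69, adjusted p = 0.0203), with single probes (-4.98, adjusted p = 0.0227), with arrays 1a and 1b kept apart (-3.68, adjusted p = 0.0351) and, chosen after seeing the data, with a signal trend (-3.72, adjusted p = 0.0453). In simulated data, where 50 genes differed by each of 4 amounts, 88.0% of those that differed by a log2 ratio of 2 were recovered and 48.0% of those that differed by 1. The adjustment is stricter where few genes differ. The 0 calls and the number of small p-values below chance therefore do not show that the factors act alike. The smallest p-values belonged to the introduced genes themselves. Neurod1 was lower with neurogenin3 by a log2 difference of -3.72 ± 0.38 (SE, adjusted p = 0.138) and Neurog3 higher by 4.07 ± 0.47 (SE, adjusted p = 0.154), with no overlap of the groups, and adjusted over the list of islet transcription factors alone both passed. The probes of Neurod1 differed by -4.98, -2.80 and, for the dimmest, 0.54. Chgb was among the 10 genes with the smallest p-values, at 1.33 ± 0.18 (SD, n = 4) with neurogenin3 and 0.03 ± 0.52 (SD, n = 3) with neuroD1, a difference of 1.30 ± 0.24 (SE, adjusted p = 0.890) that passed adjusted over the hormone and granule list alone. Its 2 probes had means of 1.74 and 0.92 with neurogenin3 and of -0.64 and 0.33 with neuroD1. Actl7a, at -1.43 ± 0.23, Ms4a8a, at -1.18 ± 0.25, Dcc, at -0.99 ± 0.21, 1110019C06Rik, at -0.88 ± 0.18, and Capza3, at -0.74 ± 0.15, were lower with neurogenin3, and 4921531C22Rik, at 0.91 ± 0.17, and Tmem238, at 0.79 ± 0.14, were higher (SE, adjusted p of 0.865 for Actl7a and 0.890 for the others). The probes of 4921531C22Rik disagreed, with a difference of 0.23 on the brighter, at a log2 signal of 5.48, and of 1.66 on the other, at 2.71.

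Outside the lists of islet transcription factors and of hormones and granule proteins, no list had a member that passed for the difference, over all genes or adjusted over the list alone. The cell cycle list lay higher with neurogenin3 as a whole, with a median difference of 0.18 over 40 genes and 33 of them above 0 (camera adjusted p = 0.00051, on 38 of the 40). That call was lost with an estimated correlation (adjusted p = 0.515) and with fry (adjusted p = 0.468), and at the preset correlation without neurogenin3 experiment 4 (adjusted p = 0.0604). Cdc6, a replication licensing gene, differed by 0.68 ± 0.15 and Cdk4 by 0.40 ± 0.13 (SE, adjusted p = 0.890 for both). The dimmest of the 9 Cdk4 probes, at a log2 signal of 3.31, differed by 2.00 and the others by 0.13 to 0.52. The other 14 lists missed the threshold, from the stress list (camera adjusted p = 0.0661), the E proteins (0.0876), the duct list (0.0876) and the islet transcription factors (0.117) to the interferon list (0.926). Without neurogenin3 experiment 2 the duct list (adjusted p = 0.0074) and the stress list (adjusted p = 0.0179) passed, and both were lost there with an estimated correlation (adjusted p = 0.876). The exocytosis list had a median of -0.03, a mean of 0.09 and direction up, and the interferon list a median of 0.02, a mean of 0.01 and direction down. Of the 10174 genes with a value in every experiment, 394 lay higher and 323 lower in all neurogenin3 than in all neuroD1 experiments, or 7.05%. Chance would give 5.71% if all 7 experiments spread alike. They did not, with a median SD of 0.31 for neurogenin3 and 0.13 for neuroD1, so the 7.05% cannot be read as an excess.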

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

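The fit of each group alone was fixed before the data were examined, but its use to test why fewer genes were called for neuroD1 was chosen only after the result was seen, as were the array weights, and the other tests here were chosen before theirs.

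The cell cycle list lay higher with neurogenin3 than with neuroD1 (camera adjusted p = 0.000510), a difference between the factors in a list tested directly. The call was lost with an estimated correlation (adjusted p = 0.515) and with fry (adjusted p = 0.468). Of the 35 ways to set 4 of the 7 experiments against 3, 2, the real one included, gave a camera p for this list as small as the real 3.4e-05. The other, with 3.5e-06, puts neurogenin3 experiment 1 with the neuroD1 experiments, so chance is not excluded. Without neurogenin3 experiment 4, the dimmest and most widely spread, the median difference was 0.129 in place of 0.183 and 27 of 40 genes lay above 0, which argues against that experiment as the whole cause, although the call ended (adjusted p = 0.0604). A difference in proliferation between the factors may remain as a hypothesis, and was not tested apart from these transcripts.

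With the spread shared between the groups, more genes were called for neurogenin3 (3583) than for neuroD1 (300). The order was reversed with each group fitted alone (625 against 2720), with array weights (2433 against 3777) and, per probe, in the authors' deposited table (2445 against 4854). The rise to 2720 for neuroD1 fitted alone is consistent with the wide spread of the neurogenin3 arrays, shared over both groups, hiding neuroD1 calls. The ratios shared by both factors were 1.26 to 1.33 times as large with neurogenin3, but 1.09 to 1.16 times without experiment 4, so a larger response to neurogenin3 and an effect of that experiment cannot be told apart.

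Only the neurogenin3 experiments and arrays were searched for one far from the rest, and neuroD1, with 3 experiments, was not. Of 91 results, each a group of neurogenin3 values, 13 stood out, and 9 of these had neurogenin3 experiment or array 4 apart. Chance alone flags about 5 in 100 such groups if all values spread alike. Array 4 spread more widely, with an SD of its log2 ratios of 0.95 against 0.46 to 0.82 on the other neurogenin3 arrays. The genes also share the same experiments, so the number flagged cannot be read as an excess over that rate. The value given for each flagged result is the gap to the nearest other value over the whole range. Array 4 had a median log2 signal of 5.48 against 6.57 to 6.71 on the other neurogenin3 arrays (0.884). Experiment 4 had a log2 ratio of 0.83 for Alb against 2.19 to 2.33 (0.907), of -0.82 for Bst2 against 0.63 to 0.76 (0.915), of 1.91 for Ehf against 0.33 to 0.49 (0.893) and of 1.61 for Ifi27 against 0.55 to 0.60 (0.945). It also stood apart for Nefm at -1.67 (0.962), Prl7d1 at -1.93 (0.830), Sdha at 0.53 (0.882) and Tubb3 at 0.52 (0.932), whose 3 probes had means from -0.17 to 0.25. Experiment 1 stood apart for Actl7a at -1.24 (0.834), Gadd45g at 0.50 (0.986) and Tubb5 at -0.15 (0.880), and experiment 3 for Paf1 at -4.97 (0.885).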

How the results depend on the processing

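Array weights, a signal trend in the prior variance, the unnormalized ratios, the removal of array 1a with neurogenin3 experiment 4, the fit of neurogenin3 alone without experiment 4, the set tests without the genes delivered by the virus and the overlap with array weights or separate fits were tests chosen only after the result was seen. The cause of a change was not tested except where the construction of the alternative shows it.

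The genes changed by neurogenin3 (3583) numbered 625 with each group fitted alone, 6304 of 21890 probes tested singly and 4 with neurogenin3 fitted alone without experiment 4, and 1958 to 3561 with 1 experiment left out. On the unnormalized ratios 321 were higher and 3736 lower. The genes changed by neuroD1 (300) numbered 2720 with each group fitted alone, 2749 with arrays scaled to 1 spread, 583 without the dimmest 25% of genes, 4854 probes in the authors' deposited table, 179 unnormalized, 3777 with array weights, 485 with a signal trend, 2127 without array 1a and neurogenin3 experiment 4, and 2 to 1785 with 1 experiment left out. In simulated data array weights gave 21.3% unchanged genes among the neuroD1 calls. Genes differing between neurogenin3 and neuroD1 numbered 0 to 1 with 1 experiment left out. The 1 gene was Neurod1 with arrays 1a and 1b separate (-3.68), single probes (-4.98), the median of probes (-4.69) and a signal trend (-3.72), and Neurog3 with the unnormalized ratios (5.02), array weights (4.40) and array 1a and experiment 4 left out (4.55). Over the alternatives the adjusted p of this difference lay between 0.0203 and 0.722 for Neurod1 and between 0.00091 and 0.787 for Neurog3.

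Experiments 3 and 4 of both factors share a number. Their deviations from the group means correlated at 0.097 and -0.0335, and with 2 such pairs this neither shows nor excludes shared control RNA. They were not treated as paired. With the number as a fixed replicate block over all experiments 1 gene differed between the factors (Neurod1, -4.19, adjusted p = 0.0475), with experiments 3 and 4 alone 0, and with a random block 0 (correlation 0.0677), while the genes changed by neurogenin3 numbered 3590 and the genes changed by neuroD1 291. With the random block no call of a named gene was lost.

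Gene list shifts numbered 4 for neurogenin3, 0 with an estimated correlation, 6 with fry, where the islet transcription factor (adjusted p = 0.0293) and neuronal (adjusted p = 0.0211) lists joined the 4, and 3 to 6 with 1 experiment left out. For neuroD1 there was 1, 0 with an estimated correlation, 4 with fry, where the housekeeping control list turned downwards (adjusted p = 0.0391), and 1 to 4 with 1 experiment left out. For the difference there was 1, 0 with an estimated correlation, 0 with fry, and 0 to 3 with 1 experiment left out. Without the genes delivered by the virus the shifted lists stayed the same 4, 1 and 1. The correlation of the 2 fold-change profiles (0.779) was 0.670 between experiments that share no number, which are fewer and so noisier, 0.835 without the dimmest 25% of genes, and 0.740 to 0.773 with 1 experiment left out. The overlap of the changed genes (284) was 3 at adjusted p under 0.01 (Sprr2a1, Tff3 and Cyp1b1, the last named after its value was seen), 1002 under 0.1, 1890 with array weights and 512 with each group fitted alone.

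Directions turned for Clps with neurogenin3 (-0.54 for the probe tested singly and -0.48 in the authors' deposited table), Scn3b (0.00380, single probe), Tcf4 (-0.029) and Snai2 (-0.25) on the unnormalized ratios, and Hes1 with neuroD1 (-0.17 for the single probe and in the authors' deposited table). Of 74 named calls for neurogenin3, 32 were kept with the group fitted alone, and of 29 for neuroD1, 29. Signal over background limits the dim genes, since 72.5% to 97.3% of probes exceeded the empty spots on an array.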

Other observations

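The values between experiments without a common number and without dim genes were fixed before the data were examined, but their use as tests here, the test of the dye orientation and that of the number of calls over other groupings were chosen only after the result was seen.

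The balance of higher and lower calls differed with signal. With the genes split into 4 nearly equal parts from dimmest to brightest, those lower with neuroD1 numbered 42, 120, 38 and 37 and those higher 7, 9, 23 and 24. With neurogenin3 529, 776, 458 and 270 were lower and 322, 424, 443 and 361 higher.

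The fold-change profiles of the 2 factors were similar. If control RNA shared only by experiments of the same number were the whole cause, experiments without a common number would not covary, but neurogenin3 1 and 2 with neuroD1 5 had a covariance of 0.134 against 0.140 over all experiments. The labels do not say that experiments of different numbers had separate beta-galactosidase RNA. A control shared by all of them is not tested by this covariance and stays open. The correlation of 0.835 without the dimmest 25% of genes, against 0.779 over all genes, carries no information on noise at dim spots, since such noise lowers a correlation. A dye effect of single genes may still contribute, because 0 arrays of the opposite dye orientation were in the labels, and it cannot be told apart from a response common to both factors. A response common to both factors stays open as a hypothesis.

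For the direct comparison a test over groupings carries no information, since with 0 genes called by the real one all 35 groupings of the experiments into 4 and 3 must call at least as many. The highest count of the other groupings was 0.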
